A study of Glycine max with 4 samples.

How the data were processed

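Binding sites of the protein encoded by GLYMA.06G314400 were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in soybean embryos (Glycine max, cultivar Williams 82) at the early maturation stage, when the embryo starts to store protein and oil. Per the labels' protocols, embryos were dissected from seeds, fixed with formaldehyde and sonicated, and chromatin was precipitated with an antibody raised against a peptide of this protein. The peak names in the deposited lists carry the word AREB3, a name in use for ABA-responsive-element-binding factors of the bZIP family. The series holds 4 samples, of which 2 are ChIP libraries and 2 are input libraries of chromatin set aside before precipitation, as 2 biological replicates of each. None is labelled as a control antibody library, so binding of this protein cannot be told from other signal that recurs with the antibody. A peak list was used for each of the 2 ChIP libraries. The input libraries enter only through the background inside those lists, and their own values were not analysed here.

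Bowtie 0.12.7 and MACS2 are the tools named in the submitters' processing notes, where MACS2 has no version. Peaks were called per replicate, 1 list for each ChIP library, and per the peak names with a q threshold of 0.01. Which input served as control for which ChIP library, how duplicate reads were treated and the genome build are not given in the sources used here. In the deposited lists each peak has a score, which is 10 times its −log10 q with the decimals dropped. The fold enrichment, a ratio, is the authors' value at the summit, the ChIP pileup over the local background with 1 fragment added to each. The −log10 p and −log10 q at the summit are also the authors' values, deposited for each peak, and so is the distance from the peak start to the summit. These values belong to single peaks, and they were used to describe, rank and filter peaks within a list. Coordinates are those of the lists, counted from 1, with chromosomes 1 to 20 and numbered scaffolds. Chromosome spans are taken to the end of the last peak, since chromosome lengths were not used here.

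The planned comparison of the replicates counted peaks of one list that overlapped a peak of the other by at least 1 bp. It was tested against 1000 random rotations of the replicate 2 list around each chromosome, with a one-sided permutation p. Overlapping peaks of both lists were joined into regions, and a region with at least 1 peak of each list is called shared. Its rank is the worse of its 2 rank fractions by peak p, and its summit is that of the better ranked peak. Shares have exact (Clopper-Pearson) 95% intervals. These intervals cover counting error only, and peaks and regions are not biological replicates.

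Other planned results were not run. They covered the share of regions in promoters, the share with a G-box (the core sequence bound by many bZIP factors), hexamer enrichment, G-box share by peak rank, and binding at fixed lists of genes such as storage proteins and oil body proteins. They need a genome sequence and an annotation on the build of the lists. The gene table at hand is on assembly Glycine_max_v4.0. Its genes and the peaks do not end at matching positions on several chromosomes, so no peak was assigned to a gene, and the gene encoding the precipitated protein was not looked up. By the rule set before the data were examined for this case, the 10 best shared regions are named by position instead.

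Everything beyond replicate overlap and the regions named by rank was chosen after the data were seen. This covers sharing by rank, position along chromosomes, neighbouring regions, dense windows, recovery of pileups, and the limit of 20 fragments for a high background. For the neighbour test and the first depth test, chosen in this way, the bounds were written down before their own results were computed. The fold enrichment and p of a summit together determine the ChIP pileup and the background, if p is the upper tail of a Poisson law. Pileups were taken as recovered where a whole number of fragments gave the deposited −log10 p within 0.001. That held for 100% of summits in replicate 1 and for all but 1 in replicate 2. Backgrounds lay on regular steps whose size gives the factor by which input was scaled to ChIP, and the lowest background gives the mean depth. The step rule for the fragment length was settled at the third attempt, because the first pair of rules returned 50% of the length. The rule kept gave 202 bp in replicate 1 and 195 bp in replicate 2, which are also the narrowest peak widths in the lists. A pileup limit of 404 fragments in replicate 1 and 390 in replicate 2 follows if the caller kept 1 read per position and strand, which no source used here states.

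Density along chromosomes was compared between the outer 20% at each end and the middle 20% of each span with a two-sided exact sign test over 20 chromosomes. The share of regions in the best 25% by rank was compared with Fisher's exact test, two-sided. Neighbouring summits within 1000 bp were compared with 1000 redraws that kept the number of regions in each 50 kb window, and counts in 50 kb windows with 1000 redraws that kept the number in each 1 Mb. Alternatives were stricter overlap, stricter peak thresholds, single lists, other distances and windows, and removal of summits with a high background. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used. Tested on simulated data, pileups were recovered in 100% of 20000 summits with settings near each replicate. The simulated backgrounds did not reach the high backgrounds described below. In simulated lists, 100% of 27695 planted shared peaks were found, and 0.94% of 11912 peaks placed at random overlapped. The planted peaks were moved by less than their width, so finding them checks the counting only.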

Results

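The antibody against the GLYMA.06G314400 protein enriched many sites across the genome of early maturation embryos in each of 2 biological replicates. Replicate 1 had 39821 peaks covering 15.2 Mb, and replicate 2 had 47716 peaks covering 18.0 Mb. Peaks were narrow, with a median width of 344 bp in replicate 1 and 337 bp in replicate 2. The authors' fold enrichment at the summit had a median of 6.68 in replicate 1 (interquartile range 4.85 to 10.6) and 5.23 in replicate 2 (3.83 to 8.34). The median −log10 q was 16.5 and 19.2. Unplaced scaffolds held 214 peaks in replicate 1 and 250 in replicate 2, and the remaining peaks lay on the 20 chromosomes.

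The libraries differed in depth. The lowest background, which is the mean fragment pileup of the ChIP library, was 3.00 fragments in replicate 1 and 6.36 in replicate 2. Per kb of the genome size given to the caller, the ChIP library of replicate 2 held 2.19 times the reads of replicate 1, if both were called with the same size. The input used for the replicate 2 list held 1.15 times the reads of that used for the replicate 1 list, and the number of peaks was 1.20 times as high. The read ratios cover only reads that the caller kept. The summit pileup had a median of 32 fragments in replicate 1, with a minimum of 11, and of 50 fragments in replicate 2, with a minimum of 19.

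The design asks where in the genome of the embryo the protein binds, and the replicates show which sites were found again. Most sites of replicate 1 were also peaks in replicate 2. Of the 39821 peaks of replicate 1, 36591 overlapped a replicate 2 peak (91.9%, exact 95% interval 91.6 to 92.2). Of the 47716 peaks of replicate 2, 36547 overlapped a replicate 1 peak (76.6%, 76.21 to 76.97). Random rotation of the replicate 2 list gave a mean of 3.89% for replicate 1 and at most 5.13%, with a one-sided permutation p of 0.001, the smallest that 1000 rotations can give. Shifts of the list by 20 to 200 kb, which keep the density along the chromosome, gave a mean of 6.80% and at most 7.19%. Joined together, the lists gave 50696 regions, of which 36297 were shared, 3230 had peaks of replicate 1 only and 11169 had peaks of replicate 2 only. With the 5000 best peaks of each list, 4239 regions were shared.

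The peaks of both replicates had close summits in most shared regions, and their pileups were correlated. In 35775 of them (98.6%) each replicate had 1 peak. The summits of such pairs lay a median of 22 bp apart (interquartile range 10 to 42), and 95.5% lay within 100 bp. Across shared regions, which are not independent replicates, the summit pileups of the replicates had a Spearman correlation of 0.92, and a Pearson correlation of 0.94 on the log2 scale. The Spearman correlation of fold enrichment was 0.829. Fold enrichment was higher in replicate 1 in 25559 shared regions (70.4%), with a median of 7.14 against 6.34 in replicate 2. Fold enrichment was at least 10 in both replicates in 7591 shared regions (20.9%). Among the 500 best regions of each list, 380 were common to both, and among the 100 best, 66.

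The strongest site lay on chromosome 7 from 2730422 to 2731184, where fold enrichment was 64.3 in replicate 1 and 39.1 in replicate 2. Next came a region on chromosome 3 from 23958616 to 23959777 with 46.8-fold enrichment in replicate 1 and 39.8-fold in replicate 2. The third lay on chromosome 11 from 2852695 to 2853848, with 59.3-fold and 39.7-fold enrichment. The fourth lay on chromosome 13 from 31638869 to 31639595 and reached 55.5-fold and 33.6-fold. Chromosome 8 held a pair of the 10 best regions, one from 21316621 to 21317383 with 52.8-fold and 37.2-fold enrichment and one from 16773517 to 16774532 with 64.6-fold and 31.2-fold. The region on chromosome 2 from 11676047 to 11677183 reached 62.7-fold in replicate 1 and 33.9-fold in replicate 2. On chromosome 1 the region from 8097173 to 8098191 had 52.4-fold and 37.1-fold enrichment. A neighbour on chromosome 1 from 8126578 to 8127763 had 48.5-fold and 37.2-fold. The region on chromosome 5 from 2540613 to 2541919 showed the highest fold enrichment of replicate 1, 65.7, beside 36.3 in replicate 2. The genome build of these positions is not given in the sources used here, and the genes around them were not analysed here. In these 10 regions the summits of the replicates lay 2 to 39 bp apart. Pileups there were 254 to 333 fragments in replicate 1 and 318 to 364 in replicate 2, which is up to 82.4% and 93.3% of the limit that 1 read per position and strand would set.

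Strong peaks were found in both replicates and weak peaks often in one. In the strongest 10% of each list by peak p, 100% of peaks were shared, with lower exact 95% bounds of 99.9% in both lists. In the weakest 10%, 67.0% of replicate 1 peaks (exact 95% interval 65.5 to 68.4) and 28.2% of replicate 2 peaks (27.0 to 29.5) were shared. Peaks that were shared had a median fold enrichment of 7.11 in replicate 1 and 6.32 in replicate 2, against 4.32 and 3.60 for those that were not. Among peaks with a background of at most 20 fragments, the best ranked without a counterpart lay on chromosome 9 from 42751989 to 42752300 for replicate 1, with 8.55-fold enrichment, and on chromosome 5 from 38046014 to 38046529 for replicate 2, with 9.10-fold. Both were picked after their values were seen.

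**Figure D1:**
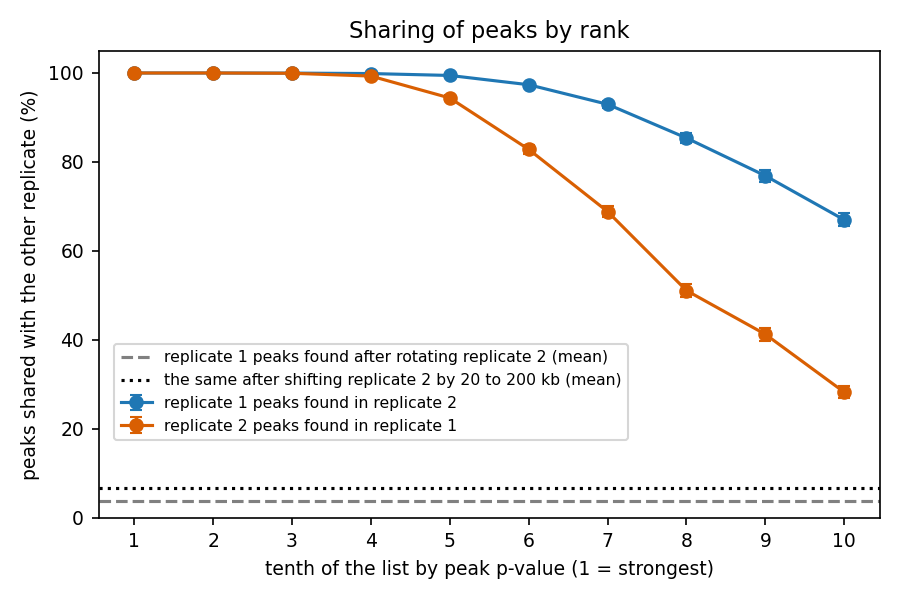
Share of peaks (%) that overlap a peak of the other replicate, in steps of 10% of the list from strongest to weakest peak p, with exact 95% intervals as bars. Replicate 1 falls from 100% to 67.0% and replicate 2 from 100% to 28.2%, and lines mark the means for replicate 1 under rotation (dashed, 3.89%) and under shifts of 20 to 200 kb (dotted, 6.80%).

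Shared regions crowded toward the ends of the chromosomes. The outer zones, 20% of the span at each end of a chromosome, held 68.5% of the shared regions on chromosomes, and the middle zone, from 40 to 60% of the span, held 6.22%. Their density was 65.7 ± 9.33 per Mb in the outer zones and 12.1 ± 15.1 per Mb in the middle zone (mean ± SD over 20 chromosomes). The density was higher in the outer zones on 19 of 20 chromosomes (exact sign test, two-sided, p = 4.01e-05). Chromosome 13 was the exception, with an outer density 0.627 times that of its middle zone and the highest density of all chromosomes, 56.7 shared regions per Mb. That outer density pooled unlike ends, with 16 shared summits in the bin starting at 1 Mb and 89 in that starting at 44 Mb. Its middle zone had 74.7 per Mb, against 17.8 per Mb on chromosome 8, the next highest. Chromosome 13 thus raised the mean and SD of the middle zone. The lowest density was 29.1 per Mb on chromosome 18. Gene density, mappability and input coverage along the chromosomes were not compared, so the crowding is not shown to be particular to this protein. The widest gap without a shared summit ran on chromosome 10 from 13791729 to 16687218, or 2.90 Mb. On chromosome 20 a gap of 2.83 Mb ran from 13737218 to 16567013. On 19 of 20 chromosomes the widest gap was centred in the inner 60% of the span, and on chromosome 13 it lay near the start, from 2840999 to 4797175. Regions of the middle zone were not detectably weaker. The best 25% of regions by rank took up 6172 of 24730 outer regions (exact 95% interval 24.4 to 25.5%) and 543 of 2247 middle regions (24.2%, 22.4 to 26.0), with a two-sided Fisher exact p of 0.415. Chromosome 13 held 685 of the middle regions, and the comparison was not repeated without it.

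**Figure D2:**
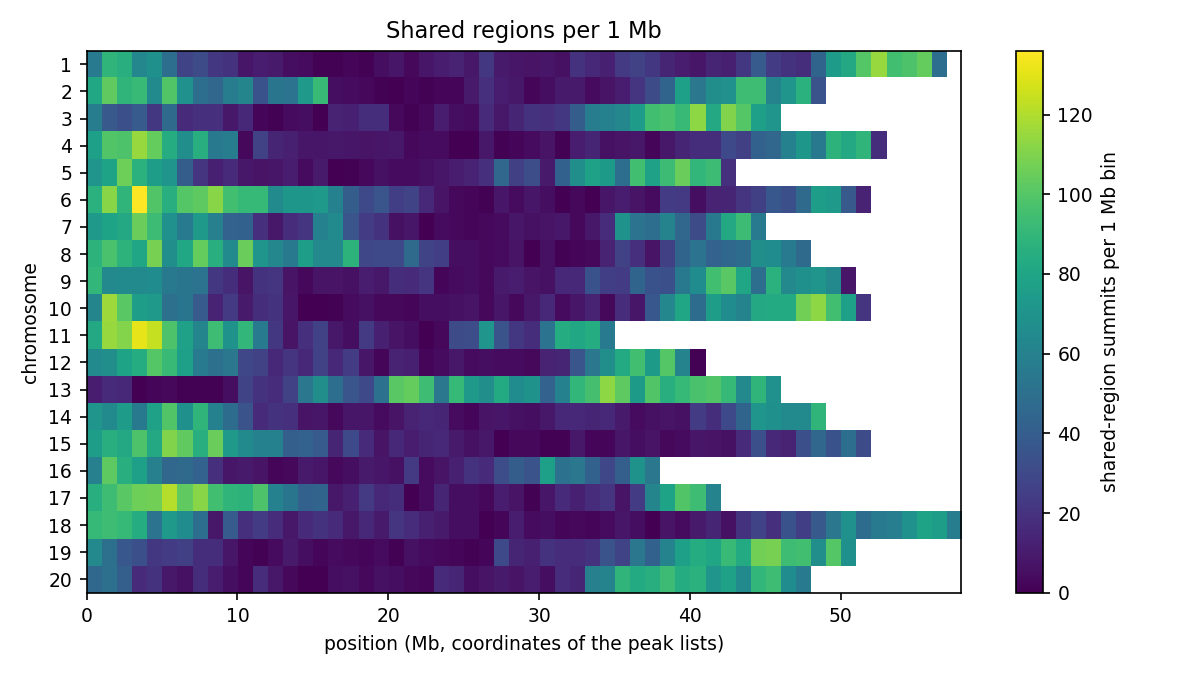
Shared-region summits per 1 Mb bin (colour) along the 20 chromosomes, with position in Mb on the horizontal axis. Bins are fullest toward the chromosome ends except on chromosome 13, where density in the outer zones was 0.627 times that in the middle zone.

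Some stretches held many sites. The densest 50 kb window was on chromosome 17 from 5300001 to 5350000, with 17 shared regions, and its strongest site reached 22.6-fold enrichment in replicate 1 and 18.9-fold in replicate 2. Windows with 16 shared regions lay on chromosome 6 from 8100001 to 8150000 and on chromosome 13 from 34650001 to 34700000. A window on chromosome 12 from 3400001 to 3450000 held 15, and one on chromosome 19 from 44000001 to 44050000 held 14. Redraws that kept the number of regions in each 1 Mb gave a fullest window of 14.4 on average and 19 at most (one-sided permutation p = 0.0470, 1000 redraws). Counts of 14 and 15 were thus near the average fullest window of the redraws. Of 18979 windows, 42.1% held no shared region and 159 held at least 10, counts that were not set against redraws. Unplaced scaffolds held 194 shared regions, 72 of them on scaffold 21, where replicate 1 had 79 peaks and replicate 2 had 88.

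**Figure D3:**
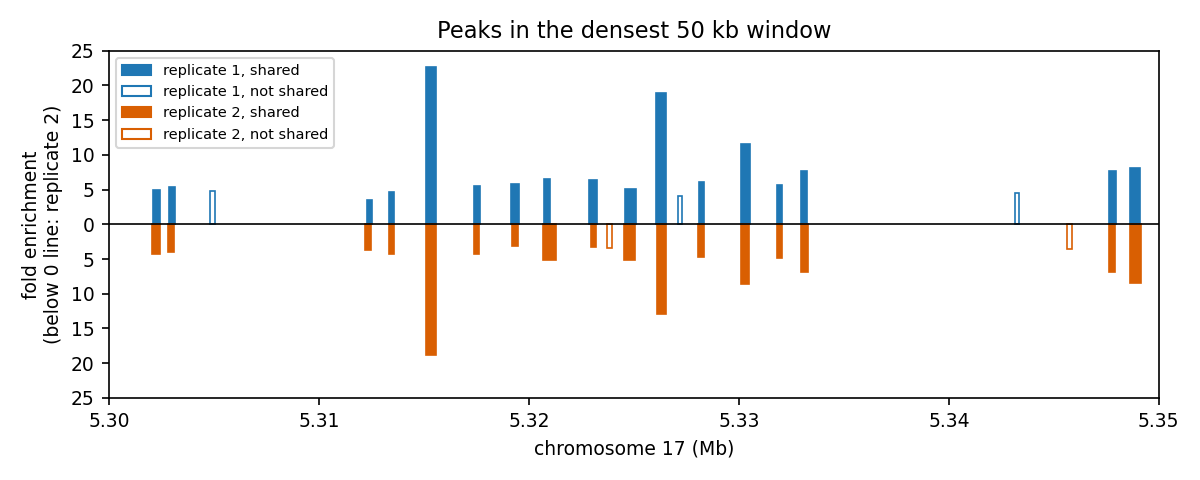
Peaks in the densest 50 kb window, on chromosome 17, with the fold enrichment of replicate 1 drawn upward and that of replicate 2 downward. Filled bars are shared peaks and open bars are not, and the replicates had 20 and 19 peaks there.

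A few sites had an unusually high input background. In replicate 1, 44 summits had a background over 20 fragments, and 2 of them were shared (4.55%, exact 95% interval 0.555 to 15.5). The 44 summits had a median background of 104.6 fragments and a median fold enrichment of 1.78. In replicate 2, 46 summits passed the same limit, 43 of them were shared, and their median fold enrichment was 3.55. These sets are unlike, since the lowest background was higher in replicate 2, where the 46 summits had a median background of 24.9 fragments. A background over 80 fragments was present at 31 summits in replicate 1 and at 1 in replicate 2. Of the 46 replicate 2 summits over 20 fragments, a cluster of 9 lay on chromosome 13 from 38798607 to 38856097, where replicate 1 had 8 peaks, and one of 6 on chromosome 19 from 43725127 to 43741454, where replicate 1 had 5. The median background at the peaks of the chromosome 13 cluster was 4.39 times the lowest background in replicate 1 and 4.60 times in replicate 2. In the chromosome 19 cluster it was 4.79 and 5.06 times.

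**Figure D4:**
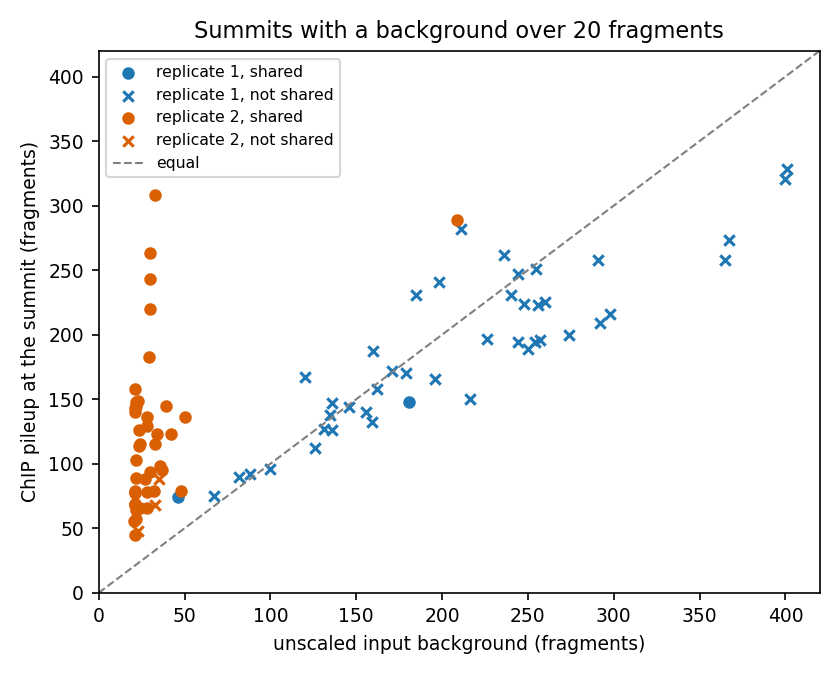
ChIP pileup at the summit against the unscaled input background, both in fragments, for the summits with a scaled background over 20 fragments (44 in replicate 1, 46 in replicate 2), with filled circles for shared summits and crosses for others. Replicate 1 lies around the dashed line of equal pileups, with a median ratio of 0.915, and replicate 2 lies mostly above it, with a median ratio of 3.55.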

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

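All alternatives other than stricter overlap, stricter q and the 5000 best peaks for replicate overlap were chosen after the data were seen. Of 36 alternatives, 31 kept the direction and the side of the threshold, or a count within 1.5 times, 4 reversed the direction and 1 moved a count. The overlap of replicate 1 peaks ranged from 84.9% with the 5000 best peaks of each list to 26434 of 27825 with q of 1e-10 or less. Shifts of 20 to 200 kb left its p at the smallest value. The overlap of replicate 2 peaks ranged from 72.6% with summits within 100 bp to 84.9% with the 5000 best peaks. With q of 1e-10 or less it was 74.2%, below the 76.6% of the main setting. Shared regions fell to 4239 with the 5000 best peaks of each list, by construction. The ratio of outer to middle density lay between 5.51 and 5.53 in single lists (without replicate 2 and without replicate 1). The difference in the share of best-ranked regions between outer and middle regions was 0.792 percentage points with shared regions, -0.0144 without replicate 1 and 0.431 without replicate 2 (Fisher exact p of 0.415, 0.982 and 0.644), 0.485 with q of 1e-10 or less and 2.40 with the 5000 best peaks of each list (Fisher exact p of 0.696 and 0.411). Close neighbours within 1000 bp made up 8.08% without replicate 2 and 9.47% without replicate 1, slightly above their redraws (two-sided permutation p of 0.284 and 0.294), and within 2000 bp 17.0% of shared neighbours against 13.9% in redraws. Joining overlapping peaks removes close pairs of shared regions by construction, but the single lists also add unshared peaks, so the part of joining was not separated. The cause of the reversals was not tested. Replicate overlap needs both lists, so neither replicate could be left out of it. Other settings for promoters, G-boxes, hexamers and gene lists were not run, for want of a matching genome. No paired analysis was possible because the input libraries were used here only as the background within the ChIP lists. At these depths a peak of one list without a counterpart is not shown to be unbound in the other replicate.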

Other observations

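Tests of the high-background summits and the later versions of the depth test were chosen after the result was seen, while the bounds of the first depth test and of the neighbour test were set before it.

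Of the replicate 2 peaks, 11169 (23.4%) had no replicate 1 peak, and lower depth of the replicate 1 ChIP library stays open as an explanation. With replicate 2 pileups scaled to the depth of replicate 1 and Poisson counting, the expected missed share was 41.8% of that observed, under the bound of 50% set beforehand as speaking against depth. That bound took any summit past the lowest peak p as called, but the narrowest peaks are 202 and 195 bp, the fitted fragment lengths, so narrower enriched stretches may have been dropped whatever their p. A version chosen later that corrected pileups for having passed the threshold gave 45.4%, also under 50%. Another that also put the calling limit at the median of the weakest 10% gave 132%, an expected 30.9% missed against 23.4% observed. That limit, a −log10 p of 7.11, is arbitrary and too high as a true one. Replicate 1 peaks were called down to 3.76. The outcome turned only with that limit, so depth and other differences between the libraries cannot be told apart here.

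Of the replicate 1 peaks, 3230 (8.11%) had no replicate 2 peak although replicate 2 was deeper. Counting noise at the depth of replicate 2 accounted for 0.452% of the observed missed share with pileups as called, 5.63% with corrected pileups and 23.6% with the higher calling limit. In all 3 versions counting noise fell short of the observed missed share for replicate 1. The higher calling limit is as arbitrary here as for replicate 2, and the share rose with each version. Pileups were also scaled by depth alone, while fold enrichment was higher in replicate 1 in 70.4% of shared regions. Counting noise is therefore not excluded beyond the limits tried, and weaker enrichment in replicate 2 was not separated from it. Of the 3230 peaks, 42 were among the summits with a high background described next. For the rest, no other technical and no biological explanation was tested.

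The 44 replicate 1 summits with a background over 20 fragments may come from the scaling of input to ChIP by 0.512, or from binding, and neither could be decided. Undoing the scaling put the input at a median of 204.5 fragments. Its maximum was 401, near the limit of 404 that 1 read per position and strand would set, and whether such a limit acted was not tested. The ratio of ChIP pileup to unscaled input had a median of 0.915, against 4.19 at other summits. By the rule first written for this ratio, scaling was met, and the objection that follows was added after the values were seen. Choosing summits by background, the denominator of this ratio, lowers it by itself. In replicate 2 it was 3.55 against 5.58, a smaller fall than in replicate 1. The median background there was 24.9 fragments against 104.6 in replicate 1, so the falls cannot be compared in size. The part of the choice was not separated, so the comparison does not decide for scaling. Binding stays open too, although the rule first written spoke against it. Of the 44 summits 4.55% were shared with replicate 2, against 89.7% of other replicate 1 peaks in the same span of ranks. But those other peaks had a median background of 3.72 fragments against 104.6. An input pileup of this height could hide binding in replicate 2 if it was present there too. The lists do not give the replicate 2 background at the unshared summits. The objection from background too was added after the value was seen.

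Neighbouring shared summits within 1000 bp made up 6.51% of neighbours, against 7.26% on average in redraws that kept the number of regions in each 50 kb window (range 6.80 to 7.63, two-sided permutation p = 0.002, the smallest possible). Joining overlapping peaks removes close pairs by construction. In the single lists, which also hold unshared peaks, the direction turned and the call was lost. The shares were 8.08% against 7.95% in redraws for replicate 1 (permutation p = 0.284) and 9.47% against 9.34% for replicate 2 (permutation p = 0.294). The part of joining was not separated. Redraws set no minimum distance, while peaks of 1 list do not overlap, so redrawn summits can lie closer than real ones. This can hide close pairs in the single lists too, so the 1000 bp comparison does not decide whether sites cluster. Within 2000 bp the share of shared regions was above the redraws, 17.0% against 13.9%.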
